A study of Mus musculus with 2 samples.

How the data were processed

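DNase-seq was carried out on mouse limb at embryonic day 14.5 as 1 group of 2 biological replicates, each 1 library from pooled male and female embryos of strain B6NCrl. Per the labels, both come from the same laboratory and were placed on the mm10 build. The labels list a pair of instrument models for replicate 2 and none for replicate 1. For each library the authors deposited a list of peaks with a signal per peak, all but 1 of them 150 bp wide, and a list of hotspots, regions with a median width of 237 bp in replicate 1 and 218 bp in replicate 2 and a smallest width of 50 bp. Every peak overlaps a hotspot of the same library by at least 1 bp. The peak signal is the authors' own value, a whole number whose scaling and normalization are not given in the sources used here. The deposited hotspot value is a −log10 q-value, running from −log10 of 0.05 to a ceiling of 100 that 33.0% of the hotspots of replicate 1 and 28.8% of those of replicate 2 reach. The aligner, the peak caller and its filters are not given in the sources used here. The peaks were called in each library separately.

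The number of reads per library is unknown, since only regions and their signals were used, so no interval or detection limit that needs read counts is given. Signals were compared within a list, and between lists only by rank over shared peaks. Intervals over peaks or genes cover sampling of those peaks or genes and not variation between animals. The labels call the libraries biological replicates (n = 2) but give both the same donor identifier, so whether they come from separate sets of embryos is not settled.

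Peaks on the autosomes and on X and Y were used, 208674 in replicate 1 and 196593 in replicate 2, and those on the mitochondrial genome and on unplaced sequence were set aside. A peak counted as shared when at least 50% of it was covered by a peak of the other replicate, and shared peaks were placed at the coordinates of replicate 1. The percentage expected by chance came from 100 seeded placements of the peaks on the same chromosome. Genes were taken from GENCODE M21 on the matching GRCm38 assembly, with 21938 protein-coding genes. A TSS window was 500 bp on each side of any annotated TSS of a protein-coding gene, and the other classes were exon, intron and intergenic sequence, in that order. A distal peak lay over 1 kb from every protein-coding TSS and was given to the nearest one within 100 kb. The territory of a gene is the sequence so given to it.

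The gene lists, intervals, motifs and tests were fixed before the data were examined. The 18 lists were limb patterning, chondrocyte, osteoblast, tendon and joint, skeletal muscle, epidermis, endothelium, erythroid, macrophage, Schwann and melanocyte, liver, heart, brain neuron, lung and gut endoderm, germ cell, photoreceptor and lens, housekeeping, and olfactory receptor genes. Every member matched a gene except Ahsp, and Ela1 matched as Cela1. No gene is in more than 1 list. TSS peaks were tested by a two-sided Fisher's exact test of members against the other protein-coding genes, and distal peaks per gene against 10000 random lists matched on decile of territory size. Interval densities were set against 1000 random intervals of the same length on the same chromosome. The two-sided p from random lists or intervals is called a permutation p. For 42 motifs, the percentage of shared distal peaks with the motif on either strand in the central 150 bp was divided by that of windows 1 kb away outside hotspots, with 1000 bootstraps over peaks for the 95% interval and an exact McNemar test. Where a motif was in no flank window, a floor of 3 windows over all flanks was used. Specific peaks were those outside every hotspot of the other replicate, tested by a two-sided Fisher's exact test. Each family was adjusted by Benjamini-Hochberg with a threshold of 0.05.

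Named genes followed a rule. From each list these were the 3 members with the most shared peaks and up to 3 in alphabetical order with no shared TSS peak. To them were added the 10 genes with the most shared distal peaks, the 5 distal peaks of highest mean signal rank, every interval, the motifs with a log2 ratio above 1 or below -0.5, and 22 genes named in advance, among them Shh, Sox9, Cdh5 and Alb. Others are said to be named after their values were seen. Some genes and 1 interval are not reported here.

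The alternatives tried were an overlap of at least 1 bp, the 50000 peaks of highest signal, hotspots in place of peaks, each replicate alone, TSS windows of 250 and 1000 bp, the outermost 5′ end only, distal peaks within 50 kb, random lists without matching, random intervals on any chromosome, flanks 3 kb away, shuffled sequence that keeps dinucleotides, and another definition of specific peaks. Added after seeing the data were the coordinates of replicate 2 and random lists matched on decile of CpG content within 500 bp of the TSS. CpG content here is the ratio of observed to expected CpGs. For a gene it is the highest ratio over its annotated TSSs, and for a peak the ratio within 250 bp of its centre. The tests were tried on simulated data of known truth. The TSS test recovered 100 of 100 lists lowered from 65% to 20%, with 1 of 100 unchanged lists called. No raised list was simulated, so how well this test recovers lists above the rest is unknown. The distal test recovered 88.0% of 3-fold and all 4-fold excesses. The interval test recovered all 50 intervals with 2.8 times the density, and the motif test all 5 motifs planted in 3% of the peaks. The test of specific peaks recovered 80.0% of lists whose replicate 1 share was raised from 57% to 72%. These simulations placed interval peaks evenly at random, used random sequence and treated peaks of a gene as independent. Real peaks cluster, so recovery in these data may be lower. Groups were not compared, because there is 1, and no test for outlying samples was made with 2 samples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, bedtools 2.31.1 and matplotlib 3.10.9 were used.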

Results

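Chromatin open to DNase I was mapped genome-wide by DNase-seq in limbs of mouse embryos at day 14.5, strain B6NCrl, with males and females pooled. At this stage the limb holds patterned mesenchyme, forming cartilage, tendon, muscle, skin, vessels and blood cells. The labels give 1 group with 2 biological replicates, which share a donor identifier, and no other tissue, so the comparisons were made between the replicates and, within them, between genes, regions and sequences. Replicate 1 has 208965 peaks of 150 bp and replicate 2 has 196870. The hotspots, mostly broader regions that the peaks overlap, cover 61.5 Mb in replicate 1 and 51.4 Mb in replicate 2, which is 2.32% and 1.94% of the genome. The median peak signal was 42 in replicate 1 and 31 in replicate 2, in the authors' own unit. The depth of each library is unknown, because no read counts were used here, so a missing peak means that none was called at this depth.

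The first comparison asked how far the replicates share their open regions. Peaks of high signal recurred in both replicates, and weak ones often did not. The strongest peak at the TSS of Sox9, the master regulator of cartilage (chromosome 11, 112782056 to 112782205), had a signal of 122 in replicate 1 and 102 in replicate 2, and the one at Hoxd13, which shapes the digits (chromosome 2, 74667936 to 74668085), had 115 and 83. At least 50% of the peak was covered by a peak of the other replicate for 127632 of 208674 peaks of replicate 1 (61.2%, 95% Wilson interval 61.0 to 61.4) and for 127727 of 196593 peaks of replicate 2 (65%, 64.8 to 65.2). Peaks placed at random on the same chromosome met that rule in 1.18% and 1.25% of cases. The shared portion rose with signal, from 14.5% in the lowest decile of replicate 1 to 97.3% in the highest, and from 16.1% to 96.6% in replicate 2. Across the 127632 shared peaks, which are not independent replicates, the signals of both lists had a Spearman's rho of 0.864 (95% bootstrap interval 0.862 to 0.865).

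**Figure D1:**
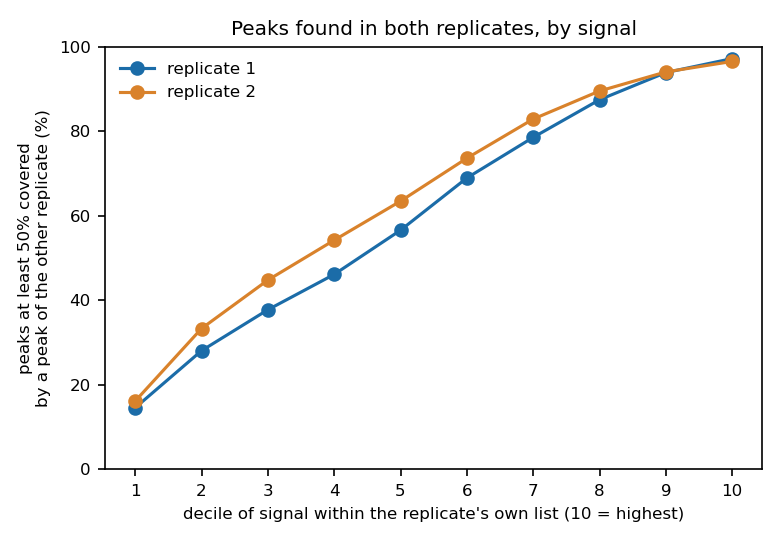
Percentage of peaks at least 50% covered by a peak of the other replicate (vertical axis) for each decile of signal within the replicate's own list (horizontal axis), 1 line per replicate. The portion rises from 14.5% to 97.3% in replicate 1 and from 16.1% to 96.6% in replicate 2.

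Shared peaks were concentrated at gene starts. Of the 127632 shared peaks, 22234 (17.4%) lay within 500 bp of an annotated transcription start site (TSS), a class that makes up 2.02% of the genome, an 8.62-fold excess. Exons outside those windows held 3.58% of the shared peaks (1.23-fold), introns 35.2% (1.02-fold) and intergenic sequence 43.8% (0.725-fold). In the replicates' own full lists the TSS class took 14.7% in replicate 1 and 15.2% in replicate 2, with an SD of 0.351 points (n = 2), and introns 36.7% and 36.1% (SD 0.478, n = 2). The 5 genes with the most shared distal peaks, those over 1 kb from any protein-coding TSS and nearest to that gene within 100 kb, were Dnm3 with 109, Frmd4a with 64, Pde4d with 62, Tenm4 with 61 and Zfhx3 with 60. Dnm3 (chromosome 1, 161982453 to 162478034) encodes a dynamin and hosts an antisense transcript that gives rise to microRNAs of skeletal mesenchyme. Ank3, Nfib, Rbms3, Auts2 and Erc2 followed with 53 to 56 each, against a mean of 3.46 and a median of 1 over 21938 protein-coding genes. A larger territory holds more peaks by chance, and this ranking was not adjusted for it. The territories of the genes named here ran from 372.5 kb at Nfib to 1535.1 kb at Pde4d.

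The next comparison asked which genes had an open TSS in the limb. Limb patterning genes, those of the epidermis and housekeeping genes were open more often than the rest, and genes of other organs, brain neurons excepted, less often. A gene was counted as open where a shared peak lay within 500 bp of a TSS, as in 14284 of the 21938 protein-coding genes (65.1%). Among limb patterning genes the count was 34 of 41 (82.9%, odds ratio 2.47, adjusted exact p = 0.0333), with 5 such peaks at Ptch1, the Hedgehog receptor, 4 at Gli3, which transmits Hedgehog signals, and 3 at Tbx4, which acts in the hindlimb. Pitx1 (hindlimb identity), Tbx5 (forelimb), Hoxa13 and Hoxd13 (the autopod) had 1 each. Shh, the signal of the posterior limb bud, Fgf8, the signal of its apical ridge, and Grem1, a BMP antagonist, had no shared TSS peak. Grem1 had 3 TSS peaks in replicate 1 and 0 in replicate 2. Among epidermal genes 22 of 25 were open (88.0%, odds ratio 3.45, adjusted exact p = 0.0333), including Trp63, the regulator of stratified epithelium, Itga6 and Lama3. The other 3 had no shared TSS peak, but Ovol1 had 5 TSS peaks in replicate 1 and 2 in replicate 2, Krt14 had 1 and 2 and Dsg3 had 0 and 1. All 25 housekeeping genes, Actb among them, were open (adjusted exact p = 0.000121). Each list's TSS peaks were tested by a two-sided Fisher's exact test of members against all other protein-coding genes, adjusted by Benjamini-Hochberg over 18 lists, of which 3 lay above the other genes and 8 below.

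The genes of the other limb cell types ranged widely. Tendon and joint genes were open in 18 of 21 cases (85.7%, adjusted exact p = 0.0964), with peaks at Scx, the tendon regulator, and Gdf5, the joint signal, and with no shared peak at Barx1, Kera and Thbs4, though Barx1 had 3 TSS peaks in replicate 1 and 1 in replicate 2. Chondrocyte genes were open in 20 of 27 cases (74.1%, adjusted exact p = 0.505): Sox9, Sox5, Sox6 and Col2a1, the collagen of cartilage, had shared TSS peaks, while Acan had no shared one, with 2 in replicate 1 and 1 in replicate 2, and Col10a1, the collagen of hypertrophic cartilage, had 0 in either replicate. Osteoblast genes reached 11 of 19 (57.9%, adjusted exact p = 0.668), with shared peaks at Runx2 and Col1a1. There was none at the mineralisation genes Bglap, Dmp1 and Ifitm5, nor at Sp7, which had 1 TSS peak in replicate 1 and 2 in replicate 2 that did not meet the rule for shared peaks. Of members named after their values were seen, Alpl, Ibsp and Phex had a shared peak and Spp1, Mepe and Mmp13 had none. Skeletal muscle genes reached 17 of 30 (56.7%, adjusted exact p = 0.474), with a shared peak at Myod1, which sets muscle fate. Ckm and Actc1 had none, although each replicate had 1 TSS peak at Ckm and 2 at Actc1. Endothelial genes reached 12 of 21 (57.1%, adjusted exact p = 0.556) and Schwann cell and melanocyte genes 12 of 18 (66.7%, adjusted exact p = 1).

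Genes of erythroid cells and macrophages were open less often than the other genes. Of the erythroid genes 5 of 19 had a shared TSS peak (26.3%, odds ratio 0.203, adjusted exact p = 0.00187), with none at Gata1, Alas2 or any globin gene. Of the macrophage genes 4 of 20 had one (20%, odds ratio 0.146, adjusted exact p = 0.000122), with none at Spi1, Adgre1 or C1qa but with 3 at Irf8. Among the lists of other organs the counts were 2 of 25 for liver (8.0%, adjusted exact p = 3.56e-08), with none at Alb, 5 of 25 for lung and gut endoderm (20%, adjusted exact p = 3.0e-05), 4 of 20 for heart (20%, adjusted exact p = 0.000122), 4 of 20 for germ cells (20%, adjusted exact p = 0.000122) and 7 of 25 for photoreceptor and lens (28.0%, adjusted exact p = 0.000434). Olfactory receptor genes had a shared TSS peak in 18 of 1135 cases (1.59%). Brain neuron genes, 14 of 25 (56.0%, adjusted exact p = 0.505), did not pass the threshold, and Neurod1 and Gad1 had no shared TSS peak.

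**Figure D2:**
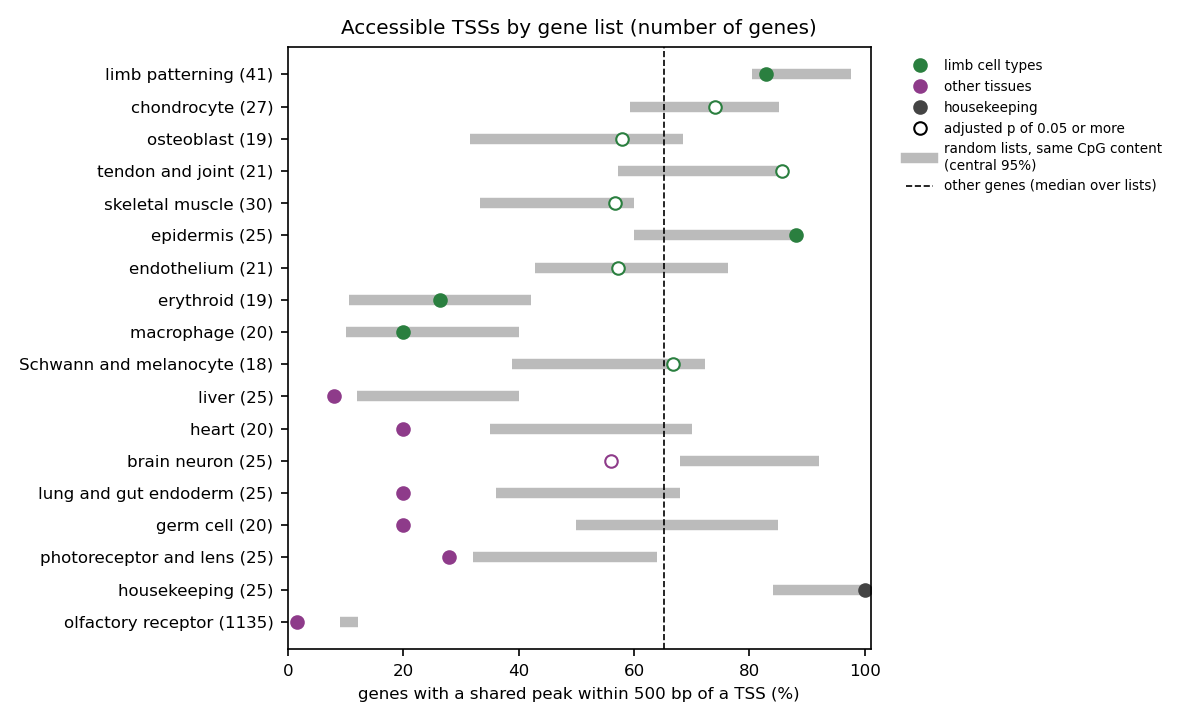
Percentage of each list's genes with a shared peak within 500 bp of a TSS (points, filled where the adjusted Fisher p is under 0.05), with the central 95% of random lists of the same CpG content (grey bars) and the median over lists of the other genes (dashed line). Limb patterning stands at 82.9% and epidermis at 88.0%, neither above its grey bar, while heart, lung and gut endoderm and germ cells at 20% lie below theirs.

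Many of these calls moved with the CpG content of the TSS windows. Against random genes of the same CpG content, a comparison chosen after seeing the data, limb patterning genes were open in 82.9% of cases where 90.5% was the mean (odds ratio 0.540, adjusted permutation p = 0.288), and epidermis (74.7%, adjusted permutation p = 0.189), erythroid (26.1%, adjusted permutation p = 1) and macrophage genes (24.7%, adjusted permutation p = 0.986) also no longer passed. The calls for liver (8.0% against 25%, odds ratio 0.303, adjusted permutation p = 0.123), photoreceptor and lens (28.0% against 46.5%, odds ratio 0.463, adjusted permutation p = 0.123) and housekeeping genes (100% against 94.2%, odds ratio 4.13, adjusted permutation p = 0.618) ended too. Heart, lung and gut endoderm, germ cell and olfactory receptor genes stayed below their matched lists (adjusted permutation p = 0.0036, 0.0024, 0.0018 and 0.0018), and brain neuron genes joined them at 56.0% against 80% (adjusted permutation p = 0.0072). The replicates taken singly also changed calls. Without replicate 1 the limb patterning list had an odds ratio of 2.15 (adjusted exact p = 0.061), and without replicate 2 the heart list had 0.648 (adjusted exact p = 0.441). Tendon and joint genes passed with either replicate alone (odds ratios 6.39 and 6.03, adjusted exact p = 0.00907 and 0.0126 without replicates 1 and 2), and so did chondrocyte genes (3.28 and 4.50, adjusted exact p = 0.0352 and 0.011).

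Distal open regions were more frequent around limb patterning genes than around random genes with territories of like size. The 41 limb patterning genes had a mean of 8.20 shared distal peaks each, 1.54 times the mean of 5.32 in 10000 random lists matched on territory size (central 95% 3.71 to 7.15, adjusted permutation p = 0.045). Ptch1 had 21 such peaks, Lmx1b, which sets dorsal fate, also 21, Gli3 18, Tbx5 and Pitx1 12 each and Tbx4 11. Lmx1b had no shared TSS peak. Shh had 5 within 100 kb, the strongest in intergenic sequence 54.1 kb from its TSS (chromosome 5, 28521276 to 28521425, signal 71 in replicate 1 and 58 in replicate 2). Olfactory receptor genes had the opposite pattern, with a mean of 0.206 against 1.21 in matched lists (0.17 times, adjusted permutation p = 0.0036).

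No list of a differentiated limb cell type passed the threshold for distal peaks, and counts at their regulators ranged widely. Tendon and joint genes had a mean of 9.95 against 6.02 (1.65 times, adjusted permutation p = 0.09), with 25 at Col12a1 and 18 each at Tnc and Thbs2, which encode matrix proteins. In the cartilage list Sox6 had 30, Sox5 24 and Sox9 16, and an intron of Col2a1 held the strongest of its 4 (chromosome 15, 97992976 to 97993125, signal 115 and 102 in replicates 1 and 2). Col1a2 had 21, Col1a1 19, Runx2 17 and Sp7 5, the strongest of which lay 10.2 kb upstream in intergenic sequence (chromosome 15, 102377296 to 102377445, signal 111 and 87). Mef2c, a muscle transcription factor, had 19, Trp63 15, Erg, an endothelial transcription factor, 21, and Cdh5, the cadherin of endothelium, 18 despite no shared TSS peak. The strongest at Cdh5 lay 78.4 kb from its TSS (chromosome 8, 104023156 to 104023305, signal 118 and 92). The macrophage regulator Spi1 had 2, Sox10, of Schwann cells and melanocytes, 1, and Gata1 had 0. The strongest peak per gene was picked after the values were seen. The other 15 lists, which include housekeeping (1.60 times), muscle (1.45 times), epidermis (1.42 times) and liver (0.669 times), had adjusted p-values from 0.282 to 0.985.

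The limb patterning call on distal peaks ended with the 50000 strongest peaks (1.62 times, adjusted permutation p = 0.101) and with hotspots (1.51 times, adjusted permutation p = 0.0648), while the tendon and joint list passed without replicate 2 (1.75 times, adjusted permutation p = 0.0372), within 50 kb (1.94 times, adjusted permutation p = 0.0054) and without matching on territory (2.87 times, adjusted permutation p = 0.0012). In simulated lists of 25 genes the test recovered 14.0% of 1.5-fold and 56.0% of 2-fold excesses, so differences of this size were often not detectable.

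**Figure D3:**
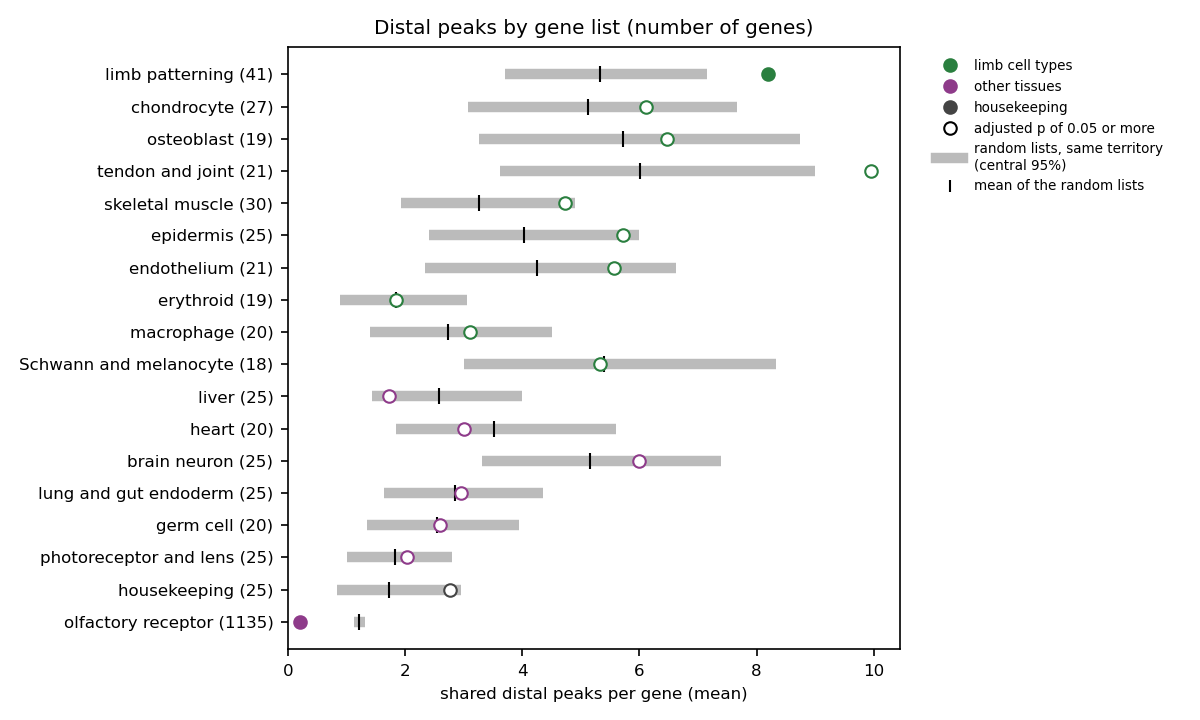
Mean number of shared distal peaks per gene of each list (points, filled where the adjusted p is under 0.05), with the mean (tick) and central 95% (grey bars) of 10000 random lists of the same territory sizes. Limb patterning genes stand at 8.20 against a random mean of 5.32, and olfactory receptor genes at 0.206 against 1.21.

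Of 21 regulatory intervals chosen for their role in limbs or as controls, the HoxA cluster and the stretch from Gdf5 to Cep250 held more shared peaks than random intervals. The 105.3 kb of HoxA (chromosome 6, 52155590 to 52260880) held 41 shared peaks, 38.9 per 100 kb against a median of 3.80 in 1000 random intervals of its length on chromosome 6 (adjusted permutation p = 0.042). It held 70 peaks in replicate 1 and 77 in replicate 2. The 11.1 kb between Gdf5 and Cep250 (chromosome 2, 155945368 to 155956457) held 7, at 63.1 per 100 kb where the random median was 0 (adjusted permutation p = 0.042). The strongest of these started at 155956176 and lay 0.2 kb from a TSS, with signals of 116 in replicate 1 and 75 in replicate 2. Those starting at 155945296 and 155945576 also lay in TSS windows. The rest were intergenic, 0.9 to 4.2 kb from a TSS. Random intervals were not matched on gene starts, where shared peaks concentrate. The comparison therefore cannot tell a high density of gene starts from a high density of other open regions, at HoxA or here. The HoxA call held under all 7 alternatives tried, each with an unadjusted permutation p of 0.002, the smallest that 1000 random intervals can give. The Gdf5 call ended under each of them, with adjusted p from 0.0629 to 0.42, the latter without replicate 1, and 0.182 without replicate 2.

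No other interval passed. The HoxD cluster held 16 shared peaks (16.5 per 100 kb, above 97.6% of random intervals, adjusted permutation p = 0.406), and the gene deserts on its telomeric and centromeric sides, which carry proximal and digit enhancers, held 85 and 54. The HoxC and HoxB clusters held 14 and 16. The digit side of HoxA held 31, the interval from Pitx1 to Macroh2a1 25 and the Runx2 gene body 35. The deserts upstream and downstream of Sox9 held 87 and 32, the stretches from Tbx5 to Tbx3 and to Rbm19 12 and 19, and the Fmn1 gene body beside Grem1 16. Between Shh and Lmbr1 there were 14 in 762.5 kb (1.84 per 100 kb against a random median of 4.85), and the Lmbr1 gene body, which holds the distant limb enhancer of Shh, had 4, all intronic. They started at 29274876, 29293316, 29314696 and 29335956 on chromosome 5, with signals of 33, 80, 35 and 69 in replicate 1 and 21, 49, 25 and 50 in replicate 2. Among the controls the beta-globin cluster had 0 in either replicate, the Myh6 and Myh7 locus 1 and the stretch from Alb to Afp 2. Adjusted p-values of these intervals ran from 0.406 to 1.

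**Figure D4:**
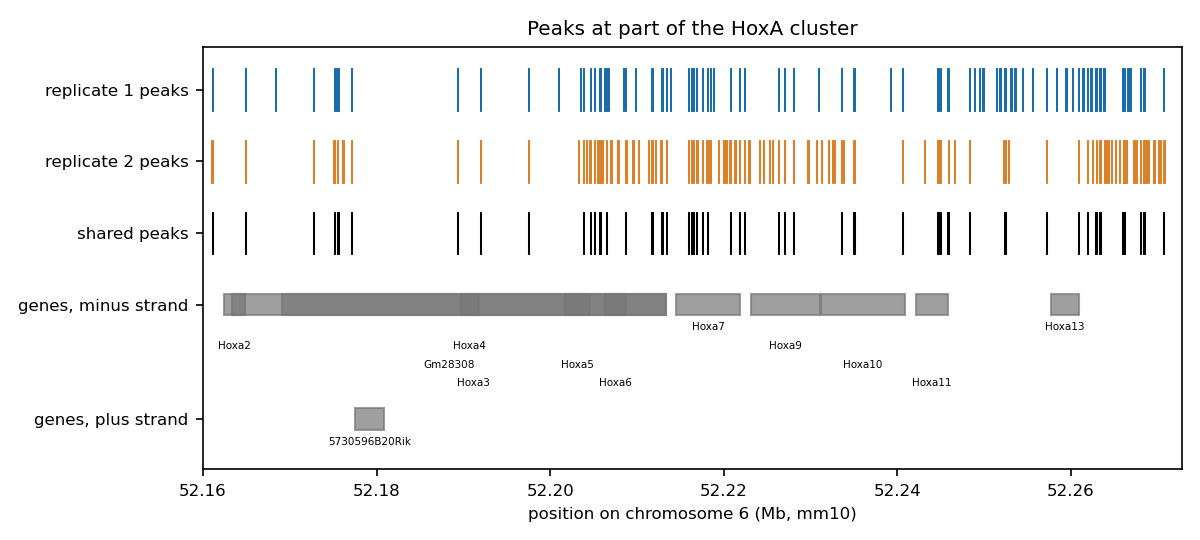
Map of part of the HoxA cluster on chromosome 6 (horizontal axis in Mb), to about 10 kb past Hoxa13, with the peaks of replicate 1, those of replicate 2, the shared peaks and the annotated genes by strand. Shared peaks recur across the part drawn, and the whole cluster holds 41.

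The sequence of distal peaks was compared with flanks 1 kb away for 42 motifs. The site of CTCF, the insulator protein, was present in 5.72% of 96846 distal peaks and 0.0294% of flanks, a log2 ratio of 7.58 (95% bootstrap interval 7.23 to 8.0). The site of REST, a repressor of neuronal genes, was in 144 peaks and in 0 of 176009 flank windows, at least 87.2-fold higher over a floor of 3 windows. The full NFI site, bound by factors that include Nfib above, followed at 6.86 (5.93 to 9.08, in 290 peaks and 4 windows). The paired E-box bound by TWIST dimers in limb mesenchyme stood at 3.20 (2.45 to 4.14), and the CAGCTG E-box used by myogenic and other bHLH factors was in 20.1% of peaks against 6.09% of flanks (1.72, 1.69 to 1.75). Sites of CREB (CRE, 2.70), NRF1 (2.20), EBF (1.51), SP and KLF factors (1.5), TEAD (1.3), AP-2 (1.16), GLI, the effectors of Hedgehog signalling (1.02), and MEF2, of muscle (1.01), were also more frequent. The exact McNemar test gave adjusted p-values of at most 5.81e-10 for each of these motifs, and the ratio of each was above 0 in either replicate's full list. The paired SOX site of cartilage enhancers had a ratio of 1.14 from 5 peaks and 4 windows (-0.85 to 2.91, adjusted exact p = 0.744). With the 50000 strongest peaks EBF at 0.37 and GLI at 0.66 no longer passed.

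Other sites were rarer in distal peaks than in flanks. Those with a log2 ratio below -0.5 included HNF1, a liver and kidney factor (-1.84, -4.64 to -0.54, from 3 peaks), and GATA (-1.16, -1.3 to -1.02). CAGGTGAG, a longer form of the ZEB and SNAI site (-0.85), and YTAATTAR, the homeodomain site around TAATTA (-0.81), were also below it. PITX (-0.80) and the paired GATA and E-box site of erythroid enhancers (-0.53) were the others. The adjusted p-values of these sites ran from 6.86e-71 for PITX to 0.0148 for HNF1. The shorter ZEB and SNAI core CAGGTG, which is CACCTG on the other strand, was not rarer in peaks. It was in 10523 of 96846 peaks and 17906 of 176009 flank windows. Against the same peaks with shuffled sequence, TAATTA stood at 0.03, PITX at 0.38 and HNF1 at 0.00, so none of them was below 0 there, and the paired GATA and E-box site at -0.14 no longer passed.

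**Figure D5:**
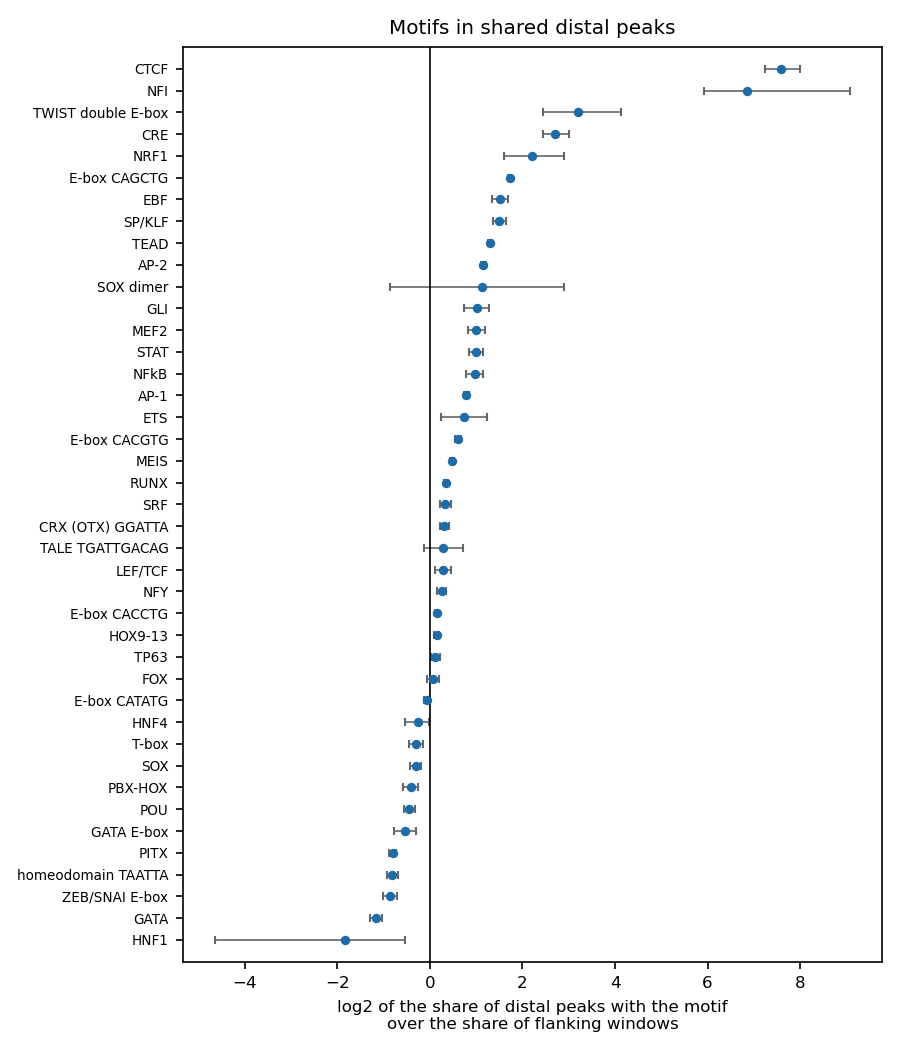
Log2 of the percentage of shared distal peaks with each motif over the percentage of flanking windows (points, with 95% bootstrap intervals as bars), REST being left out because no flank window held it. CTCF at 7.58 and NFI at 6.86 stand highest, and HNF1 at -1.84 lowest.

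The last comparison asked which genes carry the open regions found in a single replicate. Limb patterning genes carried more distal peaks specific to replicate 1, those outside every hotspot of replicate 2, than the reverse. There were 357 specific to replicate 1 and 155 specific to replicate 2, against 41457 and 30937 at all other genes (odds ratio 1.72, adjusted p = 1.46e-07, Fisher's exact test). The imbalance was seen at Msx1, a mesenchymal homeobox gene, with 32 and 3, Tbx4 with 26 and 0, Twist1 with 22 and 3, Hand2 with 22 and 5 and Meis2, a marker of the proximal limb, with 37 and 14. Hoxa13 had 7 and 15. Osteoblast genes had 141 and 61 (odds ratio 1.71, adjusted exact p = 0.0031), but 7 of them had more in replicate 1 and 7 more in replicate 2, and the 95% bootstrap interval over genes ran from 0.561 to 4.31. Dlx6 had 53 and 2 and Dlx5 12 and 0, while Runx2 had 6 and 11, Postn 3 and 10 and Cdh11 9 and 12. These genes other than Tbx4, Hoxa13 and Runx2 were named after their values were seen.

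The other 16 lists did not pass the threshold, brain neuron genes being nearest with 113 and 55 (odds ratio 1.52, adjusted exact p = 0.0589). Specific peaks were weak, with a median signal of 30 in replicate 1 and 21 in replicate 2 against 42 and 31 for all peaks of the same list. Both sides are 1 library, so the test compares these libraries only, and peaks of a gene are not independent. Random lists with like numbers of specific peaks per gene were therefore drawn. The portion of specific peaks in replicate 1 was 69.7% for limb patterning genes (central 95% of random lists 47.5 to 64.8, adjusted permutation p = 0.0408). For osteoblast genes it was 69.8% (43.2 to 69.2, adjusted permutation p = 0.348). Among the 50000 strongest peaks of each replicate no list passed the threshold. Few specific peaks remained there, 12 and 4 at limb patterning genes (odds ratio 2.75, adjusted exact p = 1, unadjusted exact p = 0.0702).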

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

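Of the tests below, those at equal numbers of peaks, of limb lists against other organs within CpG deciles and of the globin subgroups were chosen after the results were seen.

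Peaks outside the main chromosomes entered no comparison. The mitochondrial genome carried 32 peaks in replicate 1 and 30 in replicate 2, with median signals of 145 and 137, near the top of each list, and 24 were shared in each. Unplaced or unlocalised sequence carried 259 peaks in replicate 1 and 247 in replicate 2, with median signals of 36 and 27, of which 112 and 114 were shared.

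Limb patterning genes carried 357 distal peaks specific to replicate 1 and 155 specific to replicate 2, an odds ratio of 1.72 (95% interval over genes 1.19 to 2.63). Within deciles of peak CpG content it was 1.52 (1.10 to 2.32), so CpG content does not account for all of it. Among the 100000 strongest peaks of each list it was 2.65 (1.56 to 4.73, 119 and 34 peaks), so unequal numbers of peaks do not either. The hotspots that define specific peaks stayed at full, unequal extent there, 61.5 Mb in replicate 1 and 51.4 Mb in replicate 2. Unequal hotspots are therefore not excluded. Counting the peaks of a gene as independent does not account for all of it. Random lists with like numbers of specific peaks per gene reached it with permutation p = 0.0024. No test left out the genes with the largest imbalance, so how far a few genes carry it was not tested. In this list 25 genes had more in replicate 1 and 8 more in replicate 2. Such a split is not particular to it, since splits in lists that did not pass ran from 11 and 2 at macrophage genes to 10 and 10 at epidermal genes. Depth, which is unknown, and the instruments, which the labels give for replicate 2 only, stay open, as does a difference in the limbs pooled, such as their stage or their proximal and distal parts. Brain neuron genes leaned the same way with 113 and 55, 15 genes having more in replicate 1 and 4 more in replicate 2. Their portion in replicate 1, 67.3%, lay within the central 95% of random lists (43.9 to 69.4). No biological explanation was tested, because both replicates belong to 1 group.

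TSS peaks were present at 64.3% of the 241 genes of limb lists and 25.7% of the 140 genes of lists of other organs (olfactory receptors excluded), a difference of 38.6 points. Over all protein-coding genes the value was 65.1%, so the limb lists lie near it and the lists of other organs lie far below it. Genes with CpG-rich starts are open in most tissues, so CpG content is a candidate explanation. Within CpG deciles the difference was 34.9 points (95% bootstrap interval 25.6 to 45.3, permutation p = 0.0001, the smallest these permutations can give), so CpG content does not account for the whole of it. The limb lists include the erythroid and macrophage genes, which were as open as their CpG content gives. What the rest reflects stays open, as no other tissue was compared.

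No globin gene had a TSS peak in either replicate. Low CpG content is neither supported nor excluded by these counts. At the rate of genes in the same CpG deciles 0.727 of the 7 genes would have one, and the chance of 0 is 0.443. No count is lower than 0, so the comparison could not have gone against low CpG content. Repeated sequence, where reads cannot be placed, could act at Hba-a1 and Hba-a2, where 7.65% of 32-base words occur once in the genome, but not at Hbb-bh1, Hbb-y and Hba-x, where 97.9% do. Over all 7 the value was 61.3%, between the bounds set, which keeps it open at Hbb-bs and Hbb-bt. The other erythroid genes had a peak in 5 of 12 cases, where CpG content gives 4.24, and no biological explanation was tested.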

How the results depend on the processing

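The coordinates of replicate 2 and the lists matched on CpG content were chosen after the data were seen. Of 903 values recomputed under the alternatives, 775 kept their direction and their side of the threshold or moved by less than their spread. Where no cause is named below, the cause was not tested. Depth is unknown and limits every weak peak.

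With an overlap of 1 bp the shared portion was 66.6% for replicate 1 and 70.8% for replicate 2 and rho 0.856. With the 50000 strongest peaks they were 79.0%, 79.0% and 0.830, and with hotspots 58.0% and 69.7%. By class, the 50000 strongest peaks gave 37.7% at TSSs, 3.12% in exons, 24.9% in introns and 34.3% intergenic. Single replicates gave 14.7% to 15.2%, 3.66% to 4.01%, 36.1% to 36.7% and 44.5% to 45.1%. TSS windows of 250 bp gave 13.6%, 4.44%, 37.4% and 44.6%, and of 1000 bp 22.4%, 2.83%, 32.1% and 42.6%, by their width.

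For TSS peaks the number of lists above the rest was 5 with 1 bp of overlap, 1 with the 50000 strongest peaks, 1 with 250 bp windows, 0 with CpG matching and 4 to 5 with single replicates, and the number below was 5 with CpG matching. Odds ratios that crossed the threshold or 1 were as follows. With 1 bp of overlap they were 3.55 for chondrocyte and 3.96 for tendon and joint. With the 50000 strongest peaks they were 1.71 for limb patterning, 0.174 for skeletal muscle, 0.750 for epidermis (reversed), 0.208 for endothelium and 0.328 for brain neuron. With single replicates they were 2.15 to 3.68 for limb patterning, 3.28 to 4.50 for chondrocyte, 6.03 to 6.39 for tendon and joint and 0.386 to 0.648 for heart. For limb patterning they were 1.28 with hotspots, 1.78 with 250 bp windows and 1.31 with the outermost 5′ end. Epidermis had 2.83 with 250 bp windows and 1.20 with the outermost 5′ end, and tendon and joint 3.79 with 1000 bp windows and 3.66 with the outermost 5′ end. With CpG matching they were 0.540 for limb patterning (reversed), 2.29 for epidermis, 1.01 for erythroid (reversed), 0.779 for macrophage, 0.303 for liver, 0.337 for brain neuron, 0.463 for photoreceptor and lens and 4.13 for housekeeping.

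For distal peaks the number of lists above was 0 with the 50000 strongest peaks and with hotspots, 2 within 50 kb and without matching, and 1 to 2 with single replicates. Folds over random lists were 1.62 and 1.51 for limb patterning with the 50000 strongest peaks and with hotspots. For tendon and joint they were 1.94 within 50 kb, 2.87 without matching and 1.66 to 1.75 with single replicates. Intervals above random were 1, the HoxA cluster, with 1 bp of overlap, the 50000 strongest peaks, hotspots, the coordinates of replicate 2, random intervals on any chromosome and each single replicate. Lists with unequal specific peaks were 0 among the 50000 strongest peaks, where few specific peaks remain (12 and 4 for limb patterning, odds ratio 2.75, unadjusted exact p = 0.0702).

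Motif log2 ratios reversed with the 50000 strongest peaks for HOX9-13 (-0.17), TP63 (-0.085), FOX (-0.076) and LEF/TCF (-0.20), and for FOX with flanks 3 kb away (-0.033) and with replicate 2 alone (-0.0011, against 0.092 with replicate 1 alone). Against shuffled sequence they reversed for CATATG (0.78), CACCTG (-0.20), TAATTA (0.032), PITX (0.38), SRF (-0.24), TP63 (-0.084), NFY (-0.49) and POU (0.053), and HNF1 went to 0.00, which has no direction. Another 25 motif values kept their direction and crossed the threshold, 11 to pass it and 14 to miss it.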

Other observations

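The tests in this part, of motifs by list and by gene and of motifs by signal, and the count of transcripts of other types were chosen after the results were seen.

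Motifs in distal peaks differed between some lists. A pair of list and motif was tested if at least 5 of the list's peaks held the motif or at least 5 were expected to. Among 151 such pairs, 2 passed Benjamini-Hochberg adjustment of a Fisher's exact test, and 21 had an unadjusted p under 0.05. The 2 that passed met the rule only by their observed counts, with under 5 expected. Pairs left out for low counts were not in the adjustment, here or by gene below, so these adjusted p-values are too lenient. The SOX site, bound by SOX factors that act in blood vessels among others, was in 7 of 117 distal peaks of endothelial genes (5.98%) against 0.862% of those of other genes (odds ratio 7.80, adjusted exact p = 0.00597). These peaks were at Cdh5 and Tek, with 2 each, and at Kdr, a VEGF receptor, Egfl7 and Robo4. The peaks at Cdh5 lay upstream (chromosome 8, 104096736 to 104096885) and in an intron (104131696 to 104131845). The REST site was in 5 of 150 distal peaks of brain neuron genes (3.33%) against 0.137% (odds ratio 27.4, adjusted exact p = 0.000421), 1 each at Neurod2, Rbfox3, Gad1, Stmn2 and Dcx. Peaks of a gene are not independent, so these pairs were also set against random lists matched on distal peaks per gene. The means there were 0.858% for SOX and 0.153% for REST (central 95% 0.00 to 2.86 and 0.00 to 0.758, adjusted permutation p = 0.0151 for each, from an unadjusted 0.0002 that is the smallest these lists can give), and no other pair passed. REST represses such genes outside neurons, and these peaks were open in both limb replicates, the one in an intron of Gad1 (chromosome 2, 70559636 to 70559785) with a signal of 98 in replicate 1 and 75 in replicate 2.

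The strength of a distal peak went with its motifs. From the lowest to the highest of 5 equal groups by signal, the CTCF site rose from 1.37% to 14.1% of peaks. This rise did not reach the very top. By mean signal rank, 54 of the top 1000 distal peaks held the CTCF site, as did 1 of the top 30 and 0 of the top 5. Across the 5 groups the SP and KLF site rose from 0.444% to 1.90% and the REST site from 0.0101% to 0.374%. Other sites fell, among them AP-1 from 4.93% to 3.71%, HOX9 to HOX13 from 6.21% to 3.43%, PBX with HOX from 0.611% to 0.212%, LEF and TCF, the effectors of Wnt signalling, from 0.712% to 0.333%, and EBF from 1.17% to 0.374%. The AP-2 site rose from 4.54% to 7.01%, and the TWIST site was at 0.0859% and 0.0657% (adjusted exact p = 0.682). The CAGCTG E-box was most frequent in the middle group, at 21.9%, against 17.8% in the lowest and 18.7% in the highest.

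Strong distal peaks lay at annotated 5′ ends of genes of other types than protein-coding more often than distal peaks at large, a difference that was not tested. Of 99000 shared distal peaks 2.59% lay at the 5′ end of a gene of another type, as did 164 of the top 1000, 9 of the top 30 and 3 of the top 5. The 5 were nearest to Zfp324 (chromosome 7, 12949556 to 12949705), Gm42906 (chromosome 5, 151368576 to 151368725), Slc38a10 (chromosome 11, 120189976 to 120190125), Mef2d (chromosome 3, 88178056 to 88178205) and 4931414P19Rik (chromosome 14, 54603416 to 54603565). Those nearest to Gm42906, Slc38a10 and Mef2d are at the 5′ ends of 1700028E10Rik, 2810410L24Rik and 1700113A16Rik.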
